A study of Solanum chacoense with 24 samples.

How the data were processed

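Leaf RNA of the wild potato relative Solanum chacoense was measured in 24 libraries, 2 for each combination of 2 genotypes (USDA8380-1 and EE501F2_093), 2 arms (cages given Colorado potato beetles and beetle-free control cages) and 3 harvests (0, 24 and 48 h after beetle placement). Per the labels' protocols, each genotype had 6 plants at 2 per cage, with 2 treatment cages and 1 control cage, and 50 beetles were placed on plants 15 weeks old. The 0 h harvest preceded the beetles in both arms. Each library was a pool of leaf tissue that the labels call a biological replicate. Because the arms stood in different cages, a cage difference and a beetle effect are confounded within a genotype. The libraries of a genotype share plants and cages over the harvests, which the labels do not assign to libraries, and the tests treat the libraries as independent.

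Per the labels' protocols, libraries were stranded mRNA libraries sequenced as single reads of 50 nt. The submitters' processing notes name Trimmomatic 0.35, STAR 2.7.3a, Picard and HTSeq, without parameters. The genome build and annotation version are not given in the sources used here. The deposited values are counts of reads per gene, raw and not normalized, for 32917 gene identifiers in the same order in every library. The 5 summary lines that HTSeq writes below the genes were kept out of library sizes and tests. Reads outside genes made up a median of 9.86% of reads. Whether near-identical gene copies shared reads cannot be told from these counts, so single genes are uncertain in that respect.

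No file pairs the identifiers with names, so 0 of them carry a name here. The 28 gene lists fixed before the data were examined could therefore not be tested, nothing is said of gene functions, and at most 2 identifiers per direction are named in a comparison. The genes named in the comparisons were chosen by a rule fixed beforehand, without its condition on a described product, which could not be applied, and it was also used for the pooled comparison added later: the largest rises and falls in log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM and libraries of the 2 arms or genotypes that did not overlap in CPM. In the naming scheme of these identifiers the 2 digits after DM are read as the chromosome, and 98 identifiers carry a code for unplaced sequence instead.

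Genes with enough counts in the smallest group (filterByExpr) were kept, 24870 in all. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, in 1 fit of all 24 libraries with 12 groups and 12 residual degrees of freedom, followed by Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes are those implied by the quasi-likelihood statistic. CPM of single genes are on the TMM scale. Principal components used log2 CPM with a prior count of 2. Intervals of ratios are exact 95% Poisson intervals and, like a floor of 3 counts over a group, cover counting error only.

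The 11 planned comparisons were beetle against control in each genotype at 24 and 48 h, the same contrast at 0 h as a background of cage and plant differences, USDA8380-1 against EE501F2_093 at 0 h, the difference of the beetle effects between genotypes at each hour, and the change of the beetle effect from 24 to 48 h. Alternatives fixed before the data were examined were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of the compared libraries alone, the replicate number as a block, a minimum absolute log2 fold change of 1, subtraction of the 0 h contrast, and leaving out each library in turn. Added after seeing the data were a pooled beetle comparison, comparisons of each arm with its own 0 h harvest, the mean correlation of the beetle contrasts, robust dispersions, and the omission of 2 libraries (USDA8380-1 beetle 0 h replicate 3 and USDA8380-1 control 24 h replicate 2).

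On simulated counts for 24870 genes, the contrast of 2 against 2 libraries (USDA8380-1, 24 h) recovered 0% of genes changed 2-fold, 28% of those changed 4-fold, 52% of those changed 8-fold and 72% of those changed 16-fold. The genotype contrast recovered 8%, 70%, 68% and 88% of these classes, and the pooled beetle contrast 50%, 74%, 92% and 94%. False calls numbered 1 of 77, 6 of 123 and 6 of 161. These counts were drawn as independent libraries with 1 mean per gene, a spread shared by both genotypes and 50 changed genes per class. They hold no shared plants or cages and no library that stands apart in expression. The percentages and false calls therefore describe that setting and not the real comparisons.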

Results

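Gene expression was profiled in leaves of the USDA8380-1 and EE501F2_093 genotypes of Solanum chacoense to examine the response to feeding by the Colorado potato beetle. There were 12 groups of 2 libraries. Counts on genes lay between 25050119 and 51999317 in 23 of the 24 libraries and at 2114184 in the remaining one, USDA8380-1 beetle 0 h replicate 3. Replicates of a group differed by far more than counting noise. The biological coefficient of variation was 0.413 over all libraries, 0.452 within USDA8380-1 and 0.368 within EE501F2_093. Within USDA8380-1 it was 0.394 without the shallow library and USDA8380-1 control 24 h replicate 2.

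The genotype was the main axis of variation. The leading principal component, with 38.7% of the variance, separated the USDA8380-1 libraries from the EE501F2_093 libraries without overlap. The next 3 components held 10.3%, 8.6% and 8.4%. The shallow library lay apart on the third component, at 150, and USDA8380-1 control 24 h replicate 2 lay apart on the fourth, at 171. The log2 CPM of that control library correlated across genes with its replicate at r = 0.899, the lowest of the 12 groups, and 9542 genes were more than 2-fold apart between them. It held 12 genes seen almost only in USDA8380-1 at 65.6 CPM in total, against 132.6 to 363.1 in 10 other USDA8380-1 libraries. These genes were chosen for at least 2 CPM in each of those 10 libraries, which favours a lower value in the library left out. EE501F2_093 libraries had 1 to 120 counts of them. The shallow library also carried 36 genes otherwise seen almost only in EE501F2_093, at 9.16% of their EE501F2_093 mean. They reached at most 0.423% in 10 other USDA8380-1 libraries, for whose low values they were chosen.

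**Figure D1:**
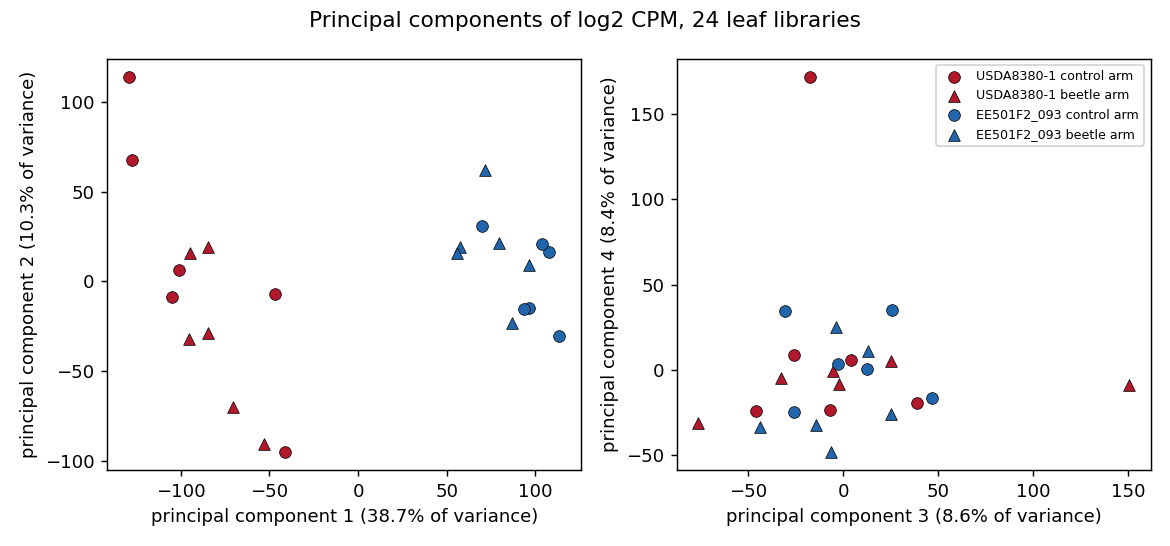
Principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM, without units, with 1 point per library, colour for genotype and shape for arm. Component 1 parts the genotypes, and 1 library of USDA8380-1 stands apart on each of components 3 and 4, at 150 and 171.

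Before any beetle was placed, leaves of USDA8380-1 and EE501F2_093 differed at 4118 of 24870 genes tested (16.6%), with 2178 genes higher in USDA8380-1 and 1940 lower. The median absolute log2 fold change of these genes was 1.95, and 3361 of them changed by at least 1 on the log2 scale. The gap was at least 5 on the log2 scale for 239 genes higher in USDA8380-1 and for 324 genes lower in USDA8380-1. These are gaps in read counts. Whether reads of both genotypes mapped equally well to these genes was not tested, so a gap need not be one of expression. Of the 4118 genes, 4095 (99.4%) kept their sign in the 24 and 48 h libraries, against 74.6% of genes not called. The harvests share plants and cages, and genes with large gaps seldom change sign, so these shares are no independent check.

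Soltu.DM.04G025110.1, on chromosome 4 by its identifier, had 14.6 ± 3.38 CPM (SD, n = 4) in USDA8380-1 at 0 h and no count in the 4 EE501F2_093 libraries, so that it was at least 612-fold higher against a floor of 3 counts over the group, and at least 497-fold by the exact 95% interval of the ratio. Its adjusted p in edgeR's quasi-likelihood test was 1.16e-05. Soltu.DM.10G007010.2 had 10.2 ± 1.32 CPM (SD, n = 4) in USDA8380-1 and 3 counts over the EE501F2_093 libraries, all in EE501F2_093 beetle 0 h replicate 1, a ratio with a 95% interval of 168 to 2395 (edgeR adjusted p = 1.16e-05). Its fitted log2 fold change was 9.76, and 11.40 without that library.

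In the other direction, Soltu.DM.12G016430.1 had 16.8 ± 2.60 CPM (SD, n = 4) in EE501F2_093 at 0 h and 1 count over the USDA8380-1 libraries, which lay in the shallow library. The interval of that ratio was 301 to 66226 (edgeR adjusted p = 4.05e-06). Its fitted log2 fold change was -10.58, with -12.20 without the shallow library, -8.76 without USDA8380-1 beetle 0 h replicate 2 and -15.78 with the replicate number as a block. Soltu.DM.09G018520.1 had 38.8 ± 4.15 CPM (SD, n = 4) in EE501F2_093 and 1.02 ± 1.95 CPM (SD, n = 4) in USDA8380-1, where 15 counts in all gave a ratio of summed counts with a 95% interval of 162 to 478 (edgeR adjusted p = 2.24e-05). That USDA8380-1 mean came mostly from the shallow library, at 3.94 CPM. The fitted log2 fold change was -9.42 (SE 0.94), with -10.80 without the shallow library, -8.32 without USDA8380-1 beetle 0 h replicate 2 and -12.84 with the block. Fitted values of genes with so few counts in a genotype depend on the prior count and are no measured folds. With the replicate number as a block, 573 genes were called, but that fit compares the genotypes at replicate 1, which USDA8380-1 lacked at 0 h. The 573 calls and the block values of both genes above therefore belong to another, extrapolated comparison. DESeq2 called 5323 genes in the comparison itself. Leaving out 1 library gave 2155 to 3437. The balance of directions turned without EE501F2_093 control 0 h replicate 2 (991 higher, 1164 lower) and without EE501F2_093 beetle 0 h replicates 1 (1297 and 1355) and 2 (1064 and 1272).

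**Figure D2:**
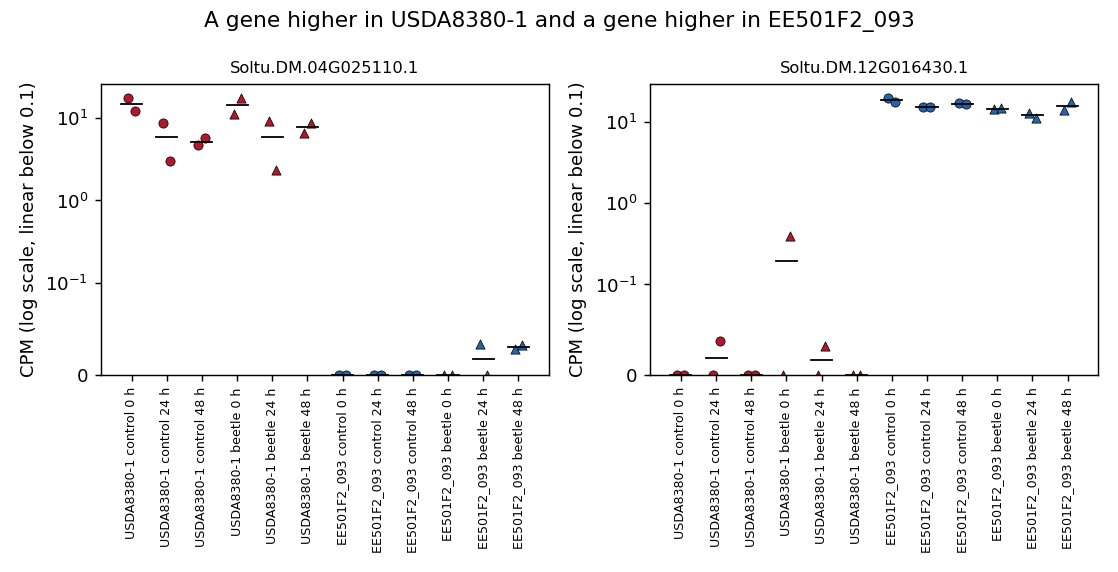
CPM (log scale, linear below 0.1) of Soltu.DM.04G025110.1 and Soltu.DM.12G016430.1 in the 12 groups, with 1 point per library and a line at the mean of the 2 libraries. Soltu.DM.04G025110.1 stood at 14.6 CPM in USDA8380-1 at 0 h and Soltu.DM.12G016430.1 at 16.8 CPM in EE501F2_093 at 0 h, each near 0 in the other genotype.

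Leaves of beetle cages were compared with leaves of the control cage at the same hour to ask which genes respond to feeding. No gene was called by edgeR in any of these 4 comparisons. Without any effect, a share of about 0.05 of the 24870 tested genes would have an unadjusted p under 0.05, here and below. Such a count does not by itself show a response, and the EE501F2_093 counts lie below that share. In USDA8380-1 at 24 h, edgeR called 0 genes, with 2876 at an unadjusted p under 0.05, and DESeq2 called 232. In USDA8380-1 at 48 h, edgeR called 0, with 1311 at an unadjusted p under 0.05, and DESeq2 called 19. In EE501F2_093 at 24 h, edgeR called 0, with 771 at an unadjusted p under 0.05, and DESeq2 called 1. In EE501F2_093 at 48 h, edgeR called 0, with 693 at an unadjusted p under 0.05, and DESeq2 called 4. The smallest adjusted p of edgeR's test were 0.341, 0.912, 1 and 1 in this order. The counts at an unadjusted p under 0.05 rest on a spread shared by both genotypes. In fits of the compared libraries alone they were 688 and 1111 in USDA8380-1 at 24 and 48 h, and 1136 and 945 in EE501F2_093. Each such fit again called 0 genes. The median SE of a log2 fold change was 0.365 to 0.366 in the 4 comparisons for genes of at least 5 CPM, from that shared spread. The biological coefficient of variation was 0.452 within USDA8380-1, 0.394 there without both libraries that stood apart, and 0.413 over all libraries. On simulated counts of independent libraries with that spread, USDA8380-1 at 24 h recovered 0% of genes changed 2-fold. The values were 28% at 4-fold, 52% at 8-fold and 72% at 16-fold. Single libraries moved the USDA8380-1 count at 24 h: it was 1886 without USDA8380-1 control 24 h replicate 1, which leaves the library that stood apart as the sole control, 100 without USDA8380-1 beetle 24 h replicate 1, and 4 without both libraries that stood apart.

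The same contrast at 0 h, when neither arm had beetles, gave the background. In EE501F2_093 edgeR called 0 genes there, with 322 at an unadjusted p under 0.05, and DESeq2 called 0. In USDA8380-1 edgeR called 1 gene, with 3227 at an unadjusted p under 0.05, and DESeq2 called 387, more than it called for USDA8380-1 with beetles. The gene called, Soltu.DM.01G040240.1, had 91.7 ± 83.8 CPM (SD, n = 2) in the plants assigned to beetles and 0.827 ± 0.247 CPM (SD, n = 2) in the control plants. Its log2 fold change was 6.78 (SE 0.90, edgeR adjusted p = 0.030). In the same control arm it averaged 21.2 CPM at 24 h and 70.3 CPM at 48 h. Group means in EE501F2_093 were 49.3 to 135.2 CPM, so the USDA8380-1 controls at 0 h were the low group. That call held in 1 of 4 fits that left out a library. It ended without the shallow library (5.26, edgeR adjusted p = 0.177), without control replicate 2 (7.11, adjusted p = 0.763) or 3 (6.49, adjusted p = 0.182), and with the replicate number as a block (6.76, adjusted p = 0.239).

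Whether the genotypes responded differently was tested as the difference of their beetle effects. At 24 h edgeR called 0 genes, with 1242 at an unadjusted p under 0.05, and DESeq2 called 16. At 48 h edgeR called 0, with 434 at an unadjusted p under 0.05, and DESeq2 called 0. For the change of the beetle effect from 24 to 48 h, edgeR called 0 genes in USDA8380-1, with 2458 at an unadjusted p under 0.05, and DESeq2 called 54. In EE501F2_093 edgeR called 0, with 213 at an unadjusted p under 0.05, and DESeq2 called 0. Without USDA8380-1 control 24 h replicate 1, edgeR called 42 genes for the difference between genotypes at 24 h and 381 for the change in USDA8380-1.

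Averaging the 4 beetle contrasts over both genotypes and both hours called 5 genes, all of them higher in beetle cages, with 3017 at an unadjusted p under 0.05. This pooled comparison was not planned and was added after edgeR had called 0 genes for beetles, for the difference between genotypes and for the change between hours. It was 1 of 6 poolings looked at, and the other 5 called 0: USDA8380-1 over both hours (1893 genes at an unadjusted p under 0.05), EE501F2_093 over both hours (1665), both genotypes at 24 h (2113), at 48 h (1648) and at 0 h (1472).

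Of the pooled calls, Soltu.DM.02G019450.4 had a log2 fold change of 6.09 (SE 0.94, edgeR adjusted p = 0.0490) and Soltu.DM.10G005300.1 of 2.17 (SE 0.27, edgeR adjusted p = 0.0130). The rule that chose them required non-overlapping arms, so the order of their libraries is no separate result. Leaving out 1 library moved the log2 fold change of Soltu.DM.02G019450.4 from 4.81 (without USDA8380-1 beetle 24 h replicate 2, edgeR adjusted p = 0.152) to 7.26 (without USDA8380-1 control 24 h replicate 1, edgeR adjusted p = 0.0169). Soltu.DM.02G019450.4 had 66.5 ± 91.5 CPM (SD, n = 2) in USDA8380-1 with beetles at 24 h and 2.88 ± 0.475 CPM (SD, n = 2) in EE501F2_093, against 0.0855 ± 0.121 and 0.292 ± 0.103 CPM in the controls. Before beetles it already reached 3.07 CPM in EE501F2_093 control 0 h replicate 2 and 1.97 CPM in the shallow library, while USDA8380-1 beetle 24 h replicate 1 had 1.74 CPM. Soltu.DM.10G005300.1 had 25.8 ± 4.45 CPM (SD, n = 2) in EE501F2_093 with beetles at 24 h and 6.65 ± 3.22 CPM (SD, n = 2) in the controls. It already differed between the arms of USDA8380-1 before beetles, with a log2 fold change of 1.68 (SE 0.53) and an unadjusted p of 0.00622, which did not pass the adjustment in edgeR's test (adjusted p = 0.271). The shallow library had 74.5 CPM of it and its replicate 31.0 CPM. In EE501F2_093 at 0 h Soltu.DM.10G005300.1 had 15.7 ± 1.15 CPM in the plants assigned to beetles and 8.83 ± 1.05 CPM in the controls (SD, n = 2). That log2 fold change was 0.83 (SE 0.52), with an unadjusted p of 0.131 in edgeR's test.

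No pooled call was left when the 0 h contrast was subtracted (0 genes), with the replicate number as a block (0) or in a fit of the 24 and 48 h libraries alone (0), and DESeq2 called 401 genes. For Soltu.DM.10G005300.1 the log2 fold change fell to 0.91 with the 0 h contrast subtracted (edgeR adjusted p = 0.654), and for Soltu.DM.02G019450.4 it was 7.07 (edgeR adjusted p = 0.647). With the block the values were 2.22 (edgeR adjusted p = 0.0545) for Soltu.DM.10G005300.1 and 5.66 (edgeR adjusted p = 0.230) for Soltu.DM.02G019450.4. In the fit of the 24 and 48 h libraries alone they were 2.17 and 6.09, as in the main fit (edgeR adjusted p = 0.119 and 0.152).

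**Figure D3:**
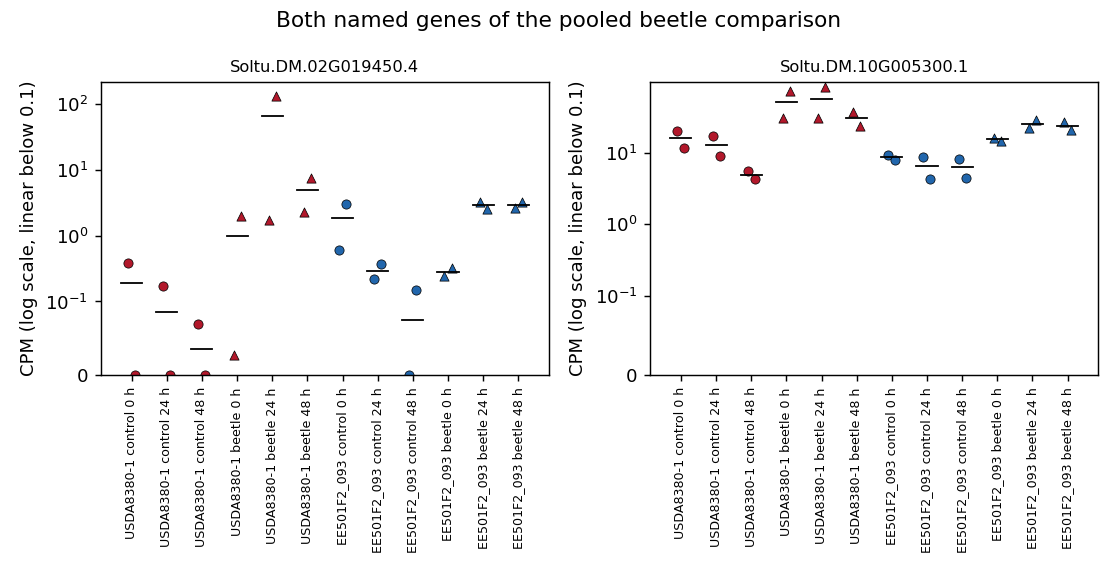
CPM (log scale, linear below 0.1) of Soltu.DM.02G019450.4 and Soltu.DM.10G005300.1 in the 12 groups, with 1 point per library and a line at the mean of the 2 libraries. The arms do not overlap at 24 and 48 h because the genes were chosen for that, and at 0 h Soltu.DM.10G005300.1 stood at 74.5 CPM in the shallow library, 31.0 CPM in the other beetle library of USDA8380-1 and 16.2 CPM on average in its control.

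Across genes, the log2 fold changes of EE501F2_093 at 24 h and 48 h correlated at r = 0.324 (Spearman 0.407) and those of USDA8380-1 at r = 0.060 (Spearman -0.091). Between genotypes r was 0.073 at 24 h and 0.169 at 48 h. For genes with a mean log2 CPM above 3 these 4 values were 0.647, -0.034, 0.269 and 0.357. The contrast at 0 h correlated with those of 24 and 48 h at 0.218 and 0.253 in EE501F2_093 and at 0.160 and -0.089 in USDA8380-1. Genes are not independent replicates, and the same plants were sampled over time. An overlap of edgeR calls does not exist with 0 calls in each of the 4 comparisons, and the overlap of DESeq2 calls was not computed.

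Each arm was also compared with its own 0 h harvest, a comparison added after seeing the data. In USDA8380-1 controls, edgeR called 30 genes at 24 h (17 higher, 13 lower) and 212 at 48 h (124 higher, 88 lower), without any beetles. In USDA8380-1 with beetles it called 2 genes at 24 h, and at 48 h 0 genes, with 1949 at an unadjusted p under 0.05. DESeq2 called 1951 genes (1048 higher, 903 lower) and 1893 (875 higher, 1018 lower) in the controls, so the balance turned at 48 h. In the beetle arm it called 586 and 97. With RLE scaling edgeR called 17 genes in the controls at 24 h (5 higher, 12 lower) and 220 at 48 h (120 higher, 100 lower). Without a filter the controls had 102 (65 higher, 37 lower) and 268 (148 higher, 120 lower). In fits of the compared libraries alone, the controls had 0 and 0 and the beetle arm 0 and 51 (45 higher, 6 lower), which turns the order of the arms at 48 h. Without both libraries that stood apart, the controls had 2 and 615 and the beetle arm 12 and 0. With the replicate number as a block, the controls had 2 and 33 and the beetle arm 0 and 0. Leaving out 1 library moved them between 0 and 3339 at 24 h and between 0 and 724 at 48 h, highest without USDA8380-1 control 24 h replicate 1 and USDA8380-1 control 48 h replicate 3. Both were 0 without USDA8380-1 control 0 h replicate 2. In the beetle arm these fits gave 1 to 502 and 0 to 529, both highest without USDA8380-1 beetle 0 h replicate 2, which leaves the shallow library alone at 0 h. In EE501F2_093 edgeR called 0 genes in both arms at both hours, with 444 to 1017 at an unadjusted p under 0.05, and DESeq2 called 3 to 31.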

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

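Every explanation in this part was tested after the values had been seen. In 20 sets of 4 libraries (the libraries of a genotype at 0 h, for 10 measures), 6 had a library far from the other 3, and 5 of the 6 concern 1 library. Chance flags about 1 in 20 sets, a rate that does not apply to Soltu.DM.10G007010.2 and Soltu.DM.12G016430.1, where the other 3 libraries had 0 counts, and the measures overlap. The EE501F2_093-only genes were chosen for low values in 10 USDA8380-1 libraries without the shallow one. Soltu.DM.09G018520.1 was chosen for a large fall in USDA8380-1. The rate does not hold for these measures either. That library, USDA8380-1 beetle 0 h replicate 3, had 2114184 counts on genes against 30641544 to 36289770 in the other USDA8380-1 libraries at 0 h. It detected 21984 genes against 25454 to 25740. Genes otherwise seen almost only in EE501F2_093 reached 38.3 CPM in it against at most 1.46. Among the named genes it held 0.394 CPM of Soltu.DM.12G016430.1, where the others had 0, and 3.94 CPM of Soltu.DM.09G018520.1, where the others had at most 0.131. The remaining case was Soltu.DM.10G007010.2 at 0.0605 CPM in EE501F2_093 beetle 0 h replicate 1, where the other 3 libraries had 0.

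The EE501F2_093-only genes were 36 genes of at least 2 CPM in every EE501F2_093 library and a median below 0.05 in 10 libraries of USDA8380-1, a rule set after seeing the data. In the shallow library they stood at 9.16% of the EE501F2_093 mean (95% Poisson interval 7.27 to 11.4), against 0.050 to 0.423% in the 10 others. In absolute terms they had 81 counts there, within the 7 to 92 of those 10 libraries, whose median was 20. Reads of EE501F2_093 misassigned in a near constant number per library are excluded only as the whole source of the 81 counts. Such a number could not much exceed the 7 counts of the lowest other library. The counts of the 10 libraries varied 23.0 times as much as counting noise (variance over mean), and their sources were not separated. Reads of EE501F2_093 present in a number that varies between libraries stay open as a candidate source, since the range is too wide for the 81 counts to decide. That this plant tissue itself switched these genes on is not excluded, since 100% of the 36 genes lay within the counting interval of a common share but the median expected count was only 1.54 per gene.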

How the results depend on the processing

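The pooled comparison and the mean correlation of the beetle contrasts with all their alternatives, robust dispersions and the omission of both libraries that stood apart were chosen after seeing the data. The causes of the changes below were not tested. DESeq2 called more genes: 232 and 19 for beetles in USDA8380-1 at 24 and 48 h, 1 and 4 in EE501F2_093, 387 for the 0 h contrast of USDA8380-1, 16 for the genotype difference of the response at 24 h, 54 for the change of the effect in USDA8380-1 and 401 in the pooled comparison. The 0 h contrast of USDA8380-1 called 166 genes in a fit of its libraries alone. Without both libraries that stood apart, beetles in USDA8380-1 at 24 h called 4 genes, the 0 h contrast of USDA8380-1 called 0, the change of the effect in USDA8380-1 called 1 and the pooled comparison 2. The pooled comparison called 22 genes without a filter, 1 with robust dispersions, 0 in a fit of its libraries alone and 0 with the 0 h contrast subtracted, also without both libraries.

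The labels link samples only by a replicate number, although harvests share plants and cages: in 9 of 19 pairs of groups with equal numbers the deviations of replicates correlated above 0.1, with a range of -0.345 to 0.329. With the number as a block, the 0 h contrast of USDA8380-1 called 0 and the pooled comparison 0. The genotype comparison called 573 genes in that fit, but at replicate 1, which USDA8380-1 lacked at 0 h, so it is another contrast.

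Leaving out 1 library at a time assumes that a lone library varies like the other groups. The genotype count then lay between 2155 and 3437; it was 2670 without USDA8380-1 control 0 h replicate 2, 2155 without EE501F2_093 control 0 h replicate 2, and 2652 and 2336 without EE501F2_093 beetle 0 h replicates 1 and 2. Beetles in USDA8380-1 at 24 h called 0 to 1886, with 1886 without USDA8380-1 control 24 h replicate 1, 6 without replicate 2 and 100 without USDA8380-1 beetle 24 h replicate 1. At 48 h the range was 0 to 12, with 12 without USDA8380-1 control 48 h replicate 3. The 0 h contrast of USDA8380-1 called 0 to 1265, with 1265 without USDA8380-1 beetle 0 h replicate 2, which leaves the shallow library alone. The change of the effect in USDA8380-1 called 0 to 381 and the genotype difference at 24 h 0 to 42, each highest without USDA8380-1 control 24 h replicate 1. The pooled comparison called 0 to 1082, with 1082 without USDA8380-1 control 24 h replicate 1, 207 without USDA8380-1 beetle 24 h replicate 1, 8 without USDA8380-1 control 48 h replicate 3 and 0 to 4 without each other library. The EE501F2_093 comparisons and the genotype difference at 48 h called 0 in each case. Named genes of the genotype comparison were called in every setting run. Soltu.DM.02G019450.4 was called in 2 of 16 such fits and Soltu.DM.10G005300.1 in 11 of 16. The mean correlation of the 4 beetle contrasts lay between 0.116 and 0.231, with an exact p under 0.05 in 13 of 16.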

Other observations

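The splits of samples, the mean correlation of the beetle contrasts with its arrangements and left-out libraries, and the neighbourhood of genes were tests chosen, or their bounds written down, after related results had been seen. Genes called between the genotypes lay next to each other in identifier order in 934 pairs, where 10000 shuffles within chromosomes gave 687.9 on average and at most 769 (permutation p = 0.0001, one-sided, the smallest they can give). In 67.1% of these pairs both genes had the same direction, against 50.2% for independent signs. Called genes made up between 13.9% of tested genes on chromosome 6 and 19.9% on chromosome 10.

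The split of the 8 libraries at 0 h by genotype called 4914 genes in a fit of these libraries in 2 groups. It was the 1 split of 35 with so many, the smallest share that 35 splits allow, and the highest of the others called 2. Every other split mixed the genotypes in both arms, which adds any genotype difference to the spread within arms. A chance split of these libraries is excluded at that share. Chance differences between the plants or cages of the genotypes are not, since the libraries of a genotype share plants and cages. For the pooled beetle comparison, libraries were reassigned to arms within genotype and hour and refitted with 16 libraries, where the real arrangement called 1 gene. Of 30 splits drawn, 2 called as many, the real one included, and the highest of the others called 1, a share of 0.067, so chance is not excluded. After that result was seen, the draw was extended to 75 splits, of which 2 again called as many, a share of 0.027. The 2 shares lie on different sides of 0.05; since the extension followed the sight of the first share, chance is treated as not excluded.

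From differences of mean log2 CPM, the 6 pairs of the 4 beetle contrasts of 24 and 48 h had a mean r of 0.199 across genes, and 0.146 from the fitted log2 fold changes. The pairs were unequal, from -0.030 for USDA8380-1 at 24 and 48 h to 0.363 for EE501F2_093 at 24 and 48 h. The mean was 0.328 for genes with a mean log2 CPM above 3 and 0.134 without both libraries that stood apart (exact p = 0.0494). It was 0.138, 0.149 and 0.116 without USDA8380-1 control 48 h replicate 1, USDA8380-1 beetle 24 h replicate 2 and EE501F2_093 beetle 48 h replicate 1, where the exact p rose to 0.0664, 0.0679 and 0.0602.

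Of 648 arrangements of libraries into arms within genotype and hour, 15 gave a mean as high, the real one included (exact p = 0.0231, one-sided), and the highest of the others was 0.278. These arrangements treat 24 and 48 h as separate plants although the same plants were sampled, so lasting plant differences may raise the agreement and chance is not excluded. Within 1 hour, where no harvest repeats, r between genotypes was 0.166 at 24 h (exact p = 0.278) and 0.273 at 48 h (exact p = 0.167). The smallest p that 18 arrangements allow is 0.0556. Libraries of an arm may still share plants, and the control libraries of a genotype share 1 cage, so these p are not free of such differences. An older difference between cages stays open beside a response to beetles. The correlations with the 0 h contrast of the same genotype ran from -0.089 to 0.253 over all genes, and above log2 CPM 3 they were 0.484 and 0.425 in EE501F2_093 and 0.077 and -0.342 in USDA8380-1.

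The 200 genes with the smallest p in the pooled comparison formed 20 neighbouring pairs in identifier order, against 1.74 on average and at most 9 in 10000 shuffles (permutation p = 0.0001, one-sided, the smallest they can give), so chance placement is excluded. In 19 pairs both genes were higher in beetle cages, where 12.2 would follow from the 156 of 200 genes that were higher. The longest run held 4 identifiers on chromosome 7; it was chosen after its values were seen and no member passed the threshold. Neighbouring copies that share reads or a common regulation may both give such runs, and no value here separates them, since the 20 pairs could come from either.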
